A study of Mus musculus with 11 samples.

How the data were processed

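ATAC-seq peak lists of sorted mouse alveolar macrophages were used, 1 list for each of 3 groups: naive (4 samples), KP day 15 (4 samples) and KP day 30 (3 samples), 11 samples in all. Per the labels every sample of a group shares its group's list, and whether the reads of the samples were pooled before calling is not given in the sources used here. The design text speaks of triplicates, while the labels number 4, 4 and 3 samples. Per the submitters' processing notes Bowtie2 2.3.4.1 and MACS2 2.1.1 were used with the mm10 build, with no settings given. How reads were filtered, or shifted for the transposase, is not given in the sources used here.

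Each list has the 10 columns of a narrowPeak file. The authors' score is, in nearly all peaks, the whole part of 10 times the −log10 of the q-value. The deposited lists also hold the fold over local background at the summit, a ratio, and the −log10 of the p-value and of the q-value. These columns have no headers, so their meaning was taken from the values. The lowest −log10 q was 1.41, 1.59 and 1.35, just above 1.30, the value of a q threshold of 0.05. The score, fold and p of a peak are the authors' own and were used to describe, rank or filter peaks within their list. The fold and p also served to recover the pileups and depths that are compared between lists, and the median fold is given for each list side by side.

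The summit pileup and local background of each peak were recovered from the fold, taken as pileup plus 1 over background plus 1, and the p-value, taken as the upper Poisson tail of the pileup. Every peak had a whole-number pileup that gave its p within 0.001 on the −log10 scale. At least 99.98% of the backgrounds were a multiple of 0.02, within 0.02 of a step, or equal to a floor shared by the list. Steps of 0.02 correspond to tags extended to 200 bp over a window of 10 kb, and the floor then gives the depth: 39.2, 93.5 and 82.2 tags per 10 kb of genome in the naive, day 15 and day 30 lists. These are tags as the peak caller counted them and not read numbers. On simulated peaks with the real backgrounds, 99.99%, 99.98% and 99.91% of pileups came back exactly in the naive, day 15 and day 30 lists.

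Peaks overlapped when they shared at least 1 bp. Expected overlap came from 100 shuffles of positions within chromosomes. All peaks were merged into regions, counted by which lists they came from. Gene positions came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, with 49976 genes, 21883 of them protein-coding and not mitochondrial. The table used here has no strand, transcripts or exons, so the planned promoter, exon and intron classes were replaced by gene boundary (within 1000 bp of either end of a gene), gene body and intergenic. Of the genes with a boundary peak, 96.1% or more had it at 1 end only. For peaks farther away, the nearest end of a protein-coding gene within 50 kb was used. Naive strength deciles were taken by the −log10 of the p-value.

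The 21 gene lists, the genes to be named and the alternatives were fixed before the data were examined. The lists hold 444 entries, 432 different genes in the annotation, 10 of them in more than 1 list, and 2 interferon entries had no match. For each list, the number of naive genes kept was placed among 10000 random lists matched on quintile of the naive score, and the number gained among 10000 random lists of genes without a naive boundary peak. The percentages of random lists describe these peak lists and are no test of the conditions. By chance at most 1.05 of the 21 lists are expected under 5% for each measure. Fewer are expected in practice, since the counts are small whole numbers and lists with no naive gene cannot fall under 5% for the number kept. For the number kept, 0 lists were under 5% at either time, and for the number gained at day 15, 5 were. On simulated lists of unchanged genes at day 15, 3.00% came out under 5%, and with 1 in 2 kept members removed 96.5% did, over 7591 genes. Each simulated list held more genes with a naive boundary peak than any real list except the housekeeping one, which had 22. The MHC class II and interferon lists had 6 each, so the 96.5% does not carry over to such small lists.

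Named genes followed this rule. For each comparison and list, up to 4 members, in list order, whose boundary peak status differed, and up to 2 that were kept, were named, and the alveolar macrophage list was named in full. Also named were the 10 highest scoring peaks absent from the naive list for each tumour list, the 10 leading regions in both tumour lists and not the naive list, the 10 strongest naive peaks in neither tumour list, and the 10 strongest naive peaks found at day 15 and not at day 30. The strongest peaks of each list, and the X and Y chromosome values, were chosen after their values were seen. Some genes that this rule names are not reported here. Coordinates are 1-based on mm10. Motif content was not analysed here, since no genome sequence was used.

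Wilson intervals have 95% confidence. Alternatives were another overlap (50% of both peaks, or within 500 bp), the upper part of each list by score, lists of equal length (3352 peaks), chromosomes 1 to 19 only, windows of 500 and 2500 bp, protein-coding genes only, peaks within 50 kb, unmatched random lists and deciles by width. Added after seeing the data were a list without peaks whose local background was over 5 times the floor, random lists matched on the day 15 score, list members that share a naive peak counted once, and random sets of peaks matched on strength and on lying at a gene boundary. Bootstrap intervals used 1000 resamples of peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and overlaps were checked against bedtools 2.31.1 with a difference of 0 peaks.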

Results

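Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in tissue-resident alveolar macrophages sorted from the lungs of C57BL/6 mice. The naive group had 4 samples. The other groups came from mice whose tail vein had received KP lung tumour cells, a line of lung adenocarcinoma, and whose lungs were taken 15 days (4 samples) or 30 days (3 samples) later. The question the groups address is how the accessible regions of resident macrophages differ between healthy lung and lung with early and later tumours. Each group had 1 peak list, so no value below has a replicate error. No p-value between conditions is given, and each 95% Wilson interval covers counting error over peaks only. A gene is said to have a boundary peak when a peak lay within 1000 bp of either end of the gene in the RefSeq annotation of the mm10 build, and to be gained or lost when it had a boundary peak in the later list only or in the earlier list only. A gene with one in both was kept, and in 99.1% of the 6039 genes kept at day 15 and 99.2% of the 2767 kept at day 30 a naive boundary peak overlapped a later one. These words describe peak calls and not amounts of accessibility. A boundary peak can also lie at a neighbouring or overlapping gene, and 1 peak can count for more than 1 gene.

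The naive list held 14731 peaks, the day 15 list 10861 and the day 30 list 3352, covering 5674 kb, 4062 kb and 1180 kb. Median peak widths were 342, 333 and 313 bp. Depth did not follow peak number: the genome-wide background recovered from the peak values was 39.2 tags per 10 kb in the naive list, 93.5 at day 15 and 82.2 at day 30, so that the tumour lists rested on 2.38 and 2.1 times the naive depth. The authors' fold over local background had a median of 6.80 in the naive list, 5.65 at day 15 and 5.53 at day 30, and the median summit pileup was 16, 19 and 17 tags. Peaks within 1000 bp of a gene end made up 53.2% of the naive list (95% interval 52.4 to 54.0), 58.6% of the day 15 list (57.7 to 59.5) and 75.9% of the day 30 list (74.4 to 77.3). When the top 3352 peaks of every list were taken, these shares were 74.2% (72.7 to 75.7), 74.8% (73.3 to 76.2) and 75.9% (74.4 to 77.3), with overlapping intervals. The strongest peaks of all lists included regions that do not sit at a macrophage gene, among them chromosome 2: 98666475 to 98667385, over 1 Mb from the nearest protein-coding gene, with a naive pileup of 122 tags, and chromosome 1: 24612592 to 24613278 at the gene model Gm10222, with a naive pileup of 99 tags.

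**Figure D1:**
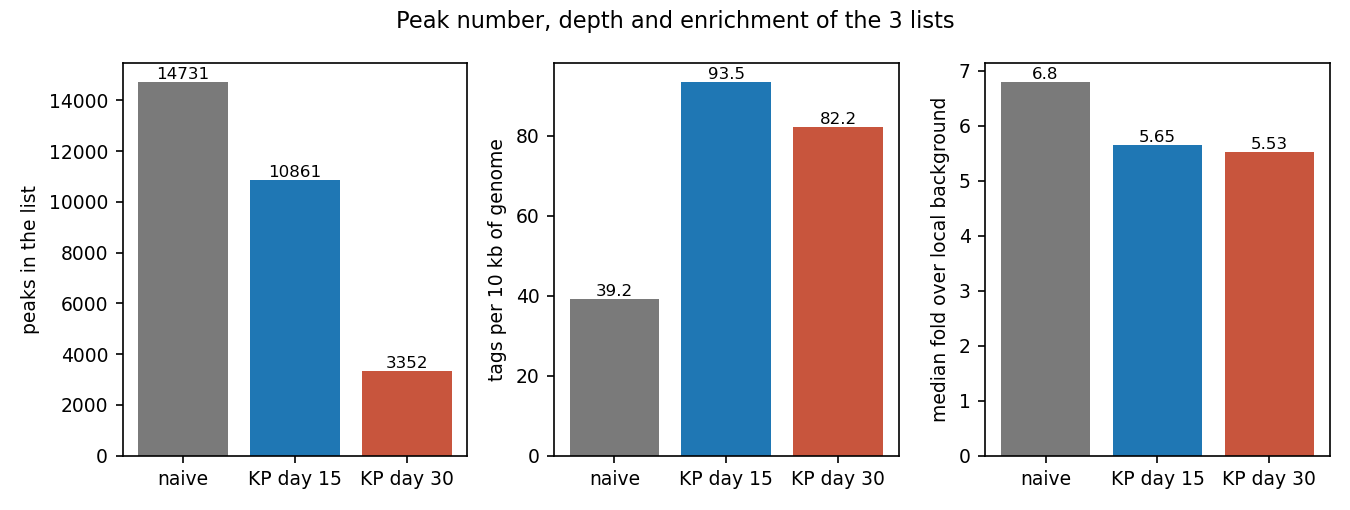
Bars show, for the naive, KP day 15 and KP day 30 lists, the number of peaks, the depth as tags per 10 kb of genome, and the median of the authors' fold over local background. The naive list has the most peaks (14731) and the highest median fold (6.80) at the lowest depth (39.2 tags per 10 kb).

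At day 15, genes of MHC class II antigen presentation had more boundary peaks than in the shallower naive list, while 7 genes of the alveolar macrophage programme no longer had one, a number not unusual for random genes of equal naive peak score. Of the 18 MHC class II genes, 6 had a boundary peak in the naive list and 9 at day 15: all 6 were kept, among them H2-Ab1, a chain of the antigen-presenting molecule, and H2-DMa, which helps to load it, and H2-Aa, H2-Eb1 and Cd74, the invariant chain, were gained. Of the 30 alveolar macrophage identity genes, 16 had a boundary peak in the naive list and 12 at day 15, with 3 gained, as many as in the MHC class II list. Of the 16, 9 were kept where 10.2 were expected at equal naive peak score, and 35.1% of random lists kept as few. Those without one at day 15 included Pparg, the nuclear receptor that drives alveolar macrophage development, the fatty acid binding protein gene Fabp5, Ear2 and the integrin gene Itgax. Their naive boundary peaks had 9, 13, 11 and 8 tags, below the naive median of 16. As nearest gene within 50 kb, Pparg had 2, 1 and 1 peaks in the naive, day 15 and day 30 lists and Ear2 3, 1 and 0. Fabp5 had 2, 0 and 0 and Itgax 1, 0 and 0. Genes kept at day 15 included the transcription factors Bhlhe40 and Cebpb. In total 6039 of the 7591 genes with a naive boundary peak were kept at day 15, 1552 were lost and 435 were gained, out of 21883 protein-coding genes. Among the top 3352 peaks of each list, where equal lengths hold the numbers of lost and gained genes close together by construction, 658 genes were lost and 707 gained, and the alveolar macrophage list had 1 naive and 1 day 15 gene and the MHC class II list 1 and 3.

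The day 15 peak at H2-Aa lay on chromosome 17 at 34287759 to 34288061, across the upper end of the gene, with a summit pileup of 16 tags. The peak at H2-Eb1 lay at 34304828 to 34305071, outside the gene and within 1000 bp of its lower end, with 15 tags. The peak at Cd74 lay on chromosome 18 at 60803603 to 60803813, just outside the lower end of the gene, with 22 tags, whereas the naive list had a peak only inside the gene at 60805840 to 60806066, with 15 tags. The peak at H2-Ab1 was present in both lists, at 34263016 to 34263215 with 9 tags and a fold of 5.38 in the naive list and at 34263017 to 34263351 with 15 tags and a fold of 3.9 at day 15. The day 15 list had 2.38 times the naive depth, and scaled to the naive depth the day 15 pileups were 6.71 tags at H2-Aa, 6.29 at H2-Eb1, 9.23 at Cd74 and 6.29 at H2-Ab1, where the lowest pileup of any naive peak was 6 tags. This scaling takes only depth into account, whereas the excess pileup (above the genome-wide background) per unit of depth also differed. In the top decile of the day 15 list its median was 0.41 of the naive value, and 99.1% of those peaks were lower than in the naive list. The scaling therefore cannot decide whether absence of the first 3 from the naive list marks a difference. At H2-Ab1 the scaled pileup was below the naive one, as at every kept gene of the list. Of 10000 random lists of genes without a naive boundary peak, 0.40% had at least 3 gained at day 15, against 0.363 expected. The count of 3 was less unusual among genes with a day 15 peak of like score, where 1.18 were expected and 9.60% of random lists had at least 3, a comparison chosen after seeing the data. Within 50 kb, 20 naive and 20 day 15 peaks were assigned to genes of the MHC class II list. Of these day 15 peaks 5 were absent from the naive list, against 3.58 expected at equal strength, and 27.3% of random sets had as many.

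**Figure D2:**
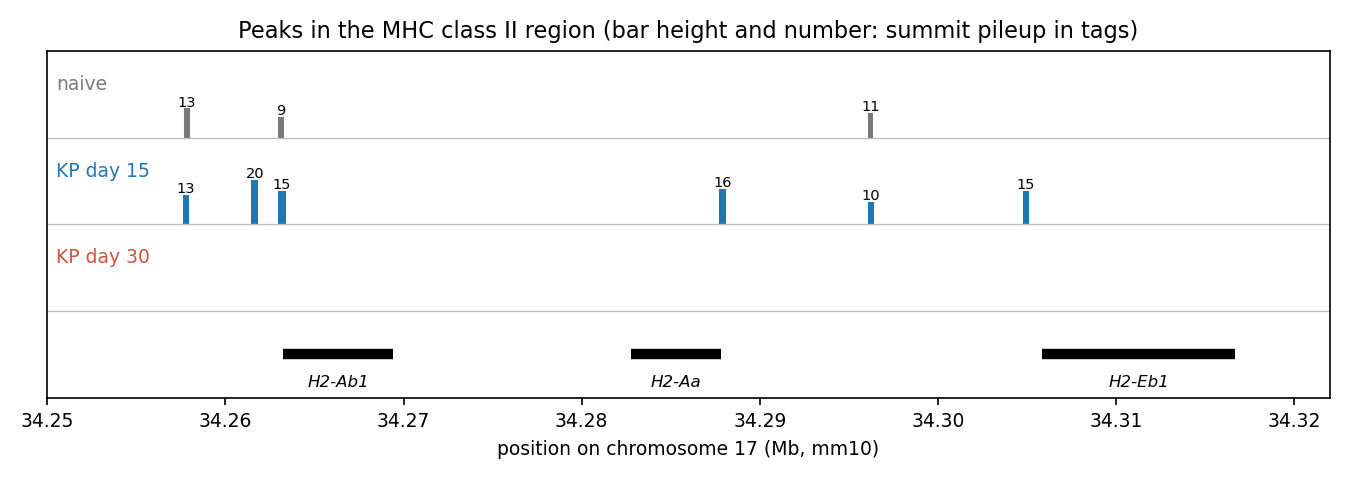
Peaks of the 3 lists along the MHC class II region of chromosome 17 (position in Mb, mm10), with bar height and number giving the summit pileup in tags, above the extents of H2-Ab1, H2-Aa and H2-Eb1. The day 15 list has peaks at H2-Aa (16 tags) and H2-Eb1 (15 tags) that are absent from the naive list, at 2.38 times the naive depth, and the day 30 list has none in the region drawn.

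Among the other macrophage lists, 12 of the 15 general macrophage and myeloid genes with a naive boundary peak were kept at day 15, including Spi1, the transcription factor PU.1, and Mertk, a receptor for dying cells. Fcgr1, Tyrobp and Ctsb were lost, and Adgre1, which encodes F4/80, was gained. With Tfec, named after its value was seen, 2 genes of the list were gained, and 3.14% of random lists had as many, or 35.6% when matched on the day 15 score. Alveolar macrophage genes gained at day 15 were Mrc1, Ctsk and Slc7a2, with 0.82% of random lists as high, or 17.6% when matched on the day 15 score. The immune regulation list had 9 genes in the naive list and 9 at day 15, with Cd274, which encodes PD-L1, and Lgals9 kept. Its members Ccl17, a chemokine for T cells, and Vsir were gained, and Lilrb4a and Socs1 were lost; 3 were gained in all, with 1.26% of random lists as high, or 8.65% when matched. Of the housekeeping genes, 22 in the naive list and 22 at day 15, 2 were gained, Chmp2a among them (0.43%, or 48.8% when matched), Rab7 and Reep5 were lost, and Gapdh and Tbp were among those kept. The 6 interferon response genes with a naive boundary peak, including Irf9, were all kept at day 15, as were the 14 hypoxia and glycolysis genes, including Epas1 and Arnt.

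The inflammatory list had 16 genes in the naive list and 15 at day 15, with Tnf and Ccl2 kept, Icam1 and Il12b lost, and Cxcl1, a neutrophil chemokine, gained. The TGF-beta and tissue remodelling list had 14 and 11, with Tgfbr1 and Tgfbr2 kept and the matrix genes Fn1, Timp2 and Spp1 lost. In the lipid list, with 15 and 14, the cholesterol exporter gene Abca1 and the liver X receptor gene Nr1h3 were lost, Soat1, which stores cholesterol as esters, was gained, and Nr1h2 and Srebf2 were kept. The naive peak counted for Nr1h3 (chromosome 2: 91183210 to 91183453) lay outside the gene and nearest to another protein-coding gene, so its loss need not concern Nr1h3. In the cell cycle list, with 14 and 13, Mki67 and Top2a were kept, Ccnb1 and Bub1 were lost and Birc5 was gained. In the activator protein 1 and immediate early list, with 17 and 14, Fosb, Nr4a2 and Klf4 were lost, Nr4a3 was gained, and Fos and Fosl2 were kept. Of the heat shock genes, 10 and 9, Hspa1a was lost and Hspa8 and Hsp90aa1 were kept. The monocyte-derived and interstitial macrophage list had 3 and 4, with Maf and Itgam kept and Itgal gained. At equal strength of the naive peak, no list among the 21 kept so few genes at day 15 that under 5% of random lists were as low. Lists with no naive gene, or with 1 as in the T cell list, could not have been so low.

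Of the day 15 peaks, 87.2% (95% interval 86.6 to 87.9) overlapped a naive peak by at least 1 bp, and 64.1% (63.3 to 64.9) of naive peaks overlapped a day 15 peak, against 0.473% and 0.346% after shuffling positions within chromosomes. The 1385 day 15 peaks absent from the naive list lay at gene boundaries in 42.5% of cases (39.9 to 45.1), inside genes in 38.9% and between genes in 18.6%. The highest scoring of these lay inside Extl3 (chromosome 14: 65097892 to 65098272, 28 tags), at Kansl3 (chromosome 1: 36368945 to 36369271, 26 tags), at Pfkl, the liver phosphofructokinase (chromosome 10: 78009656 to 78009962, 26 tags), and at Trp53inp2 (chromosome 2: 155381992 to 155382269, 29 tags). Next by score were regions inside St7, near Tra2a, at Stk35, inside the cytokine receptor gene Il31ra, in an intergenic part of chromosome 3, and at Nfya. Pfkl also had a naive boundary peak, at 78009292 to 78009491 with 10 tags, so that a region absent from the naive list can lie beside one that is in it.

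At day 30, 36.5% of all genes with a naive boundary peak still had one, and no gene list kept so many or so few that under 5% of random lists matched on naive peak score did the same. Lists with no naive gene could not reach 5%, and small lists hardly could. The interferon list kept none of its 6 genes, the lowest number possible, and 6.77% of random lists did so too. For such lists this result is no evidence that they behaved like random genes. The general macrophage list kept 5 of 15 genes where 5.09 were expected. Of 30 alveolar macrophage identity genes, 2 had a boundary peak, Bhlhe40 and Perp, against 16 in the naive list. Of the MHC class II genes 2 of 6 were kept, H2-DMa and Rfxap, and H2-Ab1, H2-DMb1, H2-DMb2 and Rfxank were lost. None of the 6 interferon response genes was kept, with Irf9, Stat2 and Ifih1 among those lost. Of the 10 heat shock genes 7 were kept, including Hspa8 and Hsp90aa1, as were 9 of the 17 activator protein 1 and immediate early genes, including Fos and Fosb, and 11 of the 22 housekeeping genes, including B2m and Rplp0.

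For genes of equal naive peak score, 4.64 kept heat shock genes were expected and 7.58% of random lists had at least 7. Hspd1 and Hspe1, both kept, rested on 1 peak in each list, and with it counted once 6 of 9 were kept and 13.3% of random lists had as many, a choice made after seeing the data. For immediate early genes 5.63 were expected and 5.25% had at least 9. For housekeeping genes 7.66 were expected and 8.71% of random lists had at least 11. At the low end, 1.67 kept interferon genes were expected and 6.77% of random lists had none, and 4.67 kept lipid genes were expected and 6.84% had as few as the 2 seen, which included the lysosomal cholesterol transporter gene Npc2. For the alveolar macrophage list 2.54 were expected where 2 were seen, and for the MHC class II list 1.21 were expected where 2 were seen. Over all genes, 2767 of 7591 were kept at day 30, 4824 were lost and 35 were gained. Among the top 3352 peaks of each list 898 were lost and 904 gained, again close by construction, and the alveolar macrophage list had 1 naive and 2 day 30 genes. Without the 214 naive peaks of high local background, a choice made after seeing the data, 131 were gained.

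Further genes lost by day 30 were Spi1, Mertk, Fcgr1 and Lyz2 in the general macrophage list, where Cd68 and Cebpa were among the 5 kept of 15, and Tnf, Ccl2, Ccl3 and Ccl4 in the inflammatory list, where Nfkbia and Rel were among the 5 kept of 16. In the immune regulation list Cd274, Lgals9, Havcr2 and Lilrb4a were lost and only Icosl was kept of 9. In the TGF-beta list Tgfbr2, Smad4, Smad7 and Ski were lost, and Tgfbr1 and Smad2 were among the 4 kept of 14. In the hypoxia list Epas1, Arnt, Hk2 and Pfkl were lost, and the glycolytic gene Pkm and Pdk1 were among the 5 kept of 14. In the lipid list Abca1, Nr1h3 (by the peak nearest to another gene), Nr1h2 and Srebf2 were lost. In the cell cycle list Mki67, Top2a, Ccnb1 and Mcm3 were lost, and Ccna2 and Ccne1 were among the 5 kept of 14. Klf2 was the only one kept of 3 in the monocyte-derived list, where Maf and Itgam were lost. Lost heat shock genes were Hspa1a, Hsp90ab1 and Bag3, lost immediate early genes included Fosl2, Egr1, Nr4a2 and Ier3, and lost housekeeping genes included Gapdh, Tbp, Hprt and Sdha.

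**Figure D3:**
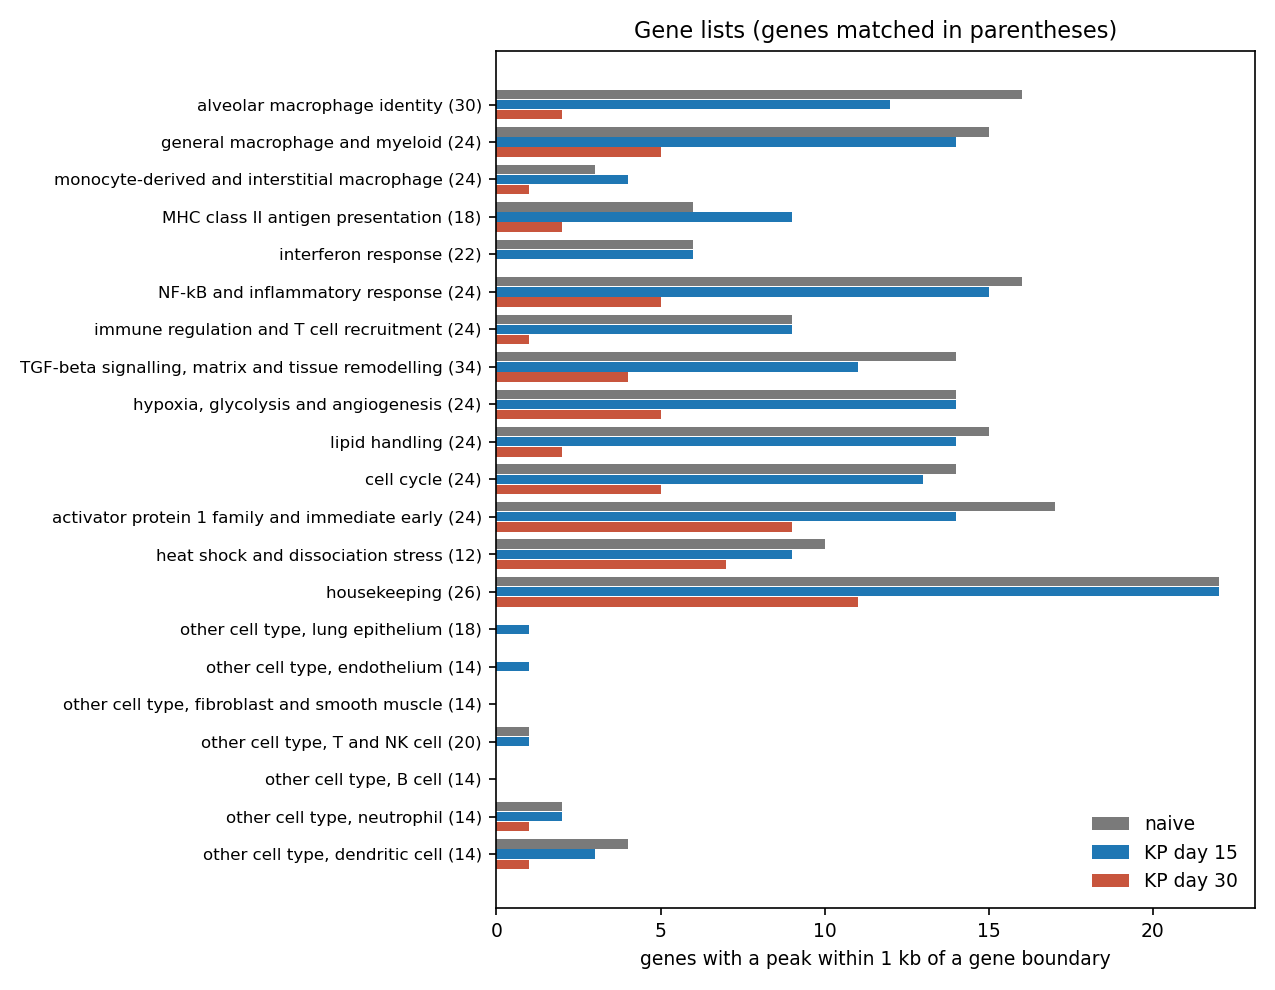
Bars show how many genes of each of the 21 gene lists (number matched in parentheses) had a peak within 1000 bp of a gene boundary in the naive, KP day 15 and KP day 30 lists. The MHC class II list goes from 6 to 9 to 2, the alveolar macrophage list from 16 to 12 to 2, and the heat shock list from 10 to 9 to 7.

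Of the day 30 peaks, 96.5% (95% interval 95.8 to 97.1) overlapped a naive peak, and 21.7% (21.0 to 22.3) of naive peaks overlapped a day 30 peak, against 0.516% and 0.116% after shuffling. With the top 3352 peaks of each list, these shares were 61.8% and 60.3%. The 117 day 30 peaks absent from the naive list were led by LOC100504180 (chromosome 10: 58225239 to 58225668, 23 tags), a region at a transfer RNA gene model near Gm5737 (chromosome 7: 120835465 to 120835970, 27 tags), and a region at the ribosomal RNA related gene model Rn18s-rs5 (chromosome 17: 39847548 to 39847912, 154 tags over a local background of 73.9). No peaks were removed here for repeated or multi-copy sequence, and whether regions at such RNA gene models reflect accessibility was not tested. Next by score were Sp140, an intergenic region near Nid1, Scand1, the intergenic region near Tra2a that was also among the leading day 15 peaks, Fam53b, Pgpep1 and Map2k2, a kinase of the MAP kinase pathway.

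Between day 15 and day 30, boundary peaks were lost at 3750 genes, kept at 2724 and gained at 78. The MHC class II genes gained at day 15, H2-Aa, H2-Eb1 and Cd74, had no boundary peak at day 30, and 7 of the 9 day 15 genes of that list were lost, among them H2-Ab1 and H2-DMb1. In the alveolar macrophage list 11 of 12 were lost, including Mrc1, Cebpb and the GM-CSF receptor genes Csf2ra and Csf2rb, and Bhlhe40 was kept. Fosb had a boundary peak in the naive and day 30 lists and not at day 15, and Fos and Jun had one in all 3. Of the day 30 peaks 94.1% (93.3 to 94.9) overlapped a day 15 peak, and of the day 15 peaks 28.7% (27.9 to 29.6) overlapped a day 30 peak, with 62.8% and 61.3% for the top 3352 peaks of each.

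Over all genes with a day 15 boundary peak, 42.1% were kept at day 30, and no number expected at equal peak score is given for the lists in this comparison. Among genes of the other lists with a day 15 boundary peak, all 6 interferon response genes, 9 of 14 hypoxia genes, 12 of 14 lipid genes and all 9 immune regulation genes had none at day 30. Of the heat shock genes 7 of 9 were kept, with Hsp90ab1 and Bag3 lost, and of the housekeeping genes 11 of 22 were kept, with Gapdh, Tbp and Hprt among the lost. The 10 strongest naive peaks found at day 15 and not at day 30 lay at Grhl1, Fggy, Ell2, Cab39l, Vrk2, Arl14ep, Ski, Rnf20, Spring1 and Ttk. Their naive pileups ran from 39 tags at Ttk to 56 at Ell2, an elongation factor of RNA polymerase II, and at Grhl1 the naive pileup was 53 tags (chromosome 12: 24571942 to 24572428).

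Merging all peaks gave 16069 regions. Of these, 3057 were in all 3 lists, 6278 in the naive and day 15 lists, 5174 in the naive list only, 1345 at day 15 only, 106 in the naive and day 30 lists, 73 at day 30 only and 36 in both tumour lists but not the naive list. Both tumour lists were set against the same naive list, so no number expected by chance is given for the 36. The smallest counts moved with the settings: the 36 became 153 without peaks of high local background (chosen after seeing the data), 146 when an overlap of 50% of both peaks was asked for and 366 with lists of equal length, and the 73 became 47 when peaks within 500 bp counted as shared, and 689 and 902 under the last 2 of the former settings. The leading regions of the 36 lay at LOC100504180, near Gm5737, near Tra2a (chromosome 6: 49236394 to 49236650, 18 tags at day 30), at Map2k2, at Scand1, at Vps26a, at Rn18s-rs5, inside Sp140, inside Pan3 and at Cisd1. The strongest naive peaks found in neither tumour list included those at Asdurf and Asnsd1 (chromosome 1: 53352374 to 53352914, 32 tags), the heme-regulated kinase gene Eif2ak1, G2e3, Mettl22 and Fam199x, at the end of a gene model that is not protein-coding with Ier5 as the nearest protein-coding gene, between genes nearest to Mmp10, and in intergenic parts of chromosomes 1 and 5.

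Weak naive peaks were the ones most often missing from the tumour lists. In the lowest decile of naive strength 25.8% of peaks (95% interval 23.6 to 28.1) were found at day 15 and 2.99% (2.23 to 3.98) at day 30, and in the highest decile 99.8% (99.4 to 99.9) and 80.1% (78.0 to 82.1). Within a decile, peaks at gene boundaries were found more often at day 30 than peaks elsewhere, with 82.6% (80.4 to 84.7) against 68.4% (62.6 to 73.8) in the highest decile and 37.7% (34.6 to 40.9) against 18.4% (15.4 to 21.8) in decile 8. Naive peaks found in both tumour lists lay at gene boundaries in 77.6% of cases (76.1 to 79.0), those found in neither in 38.6% (37.3 to 40).

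**Figure D4:**
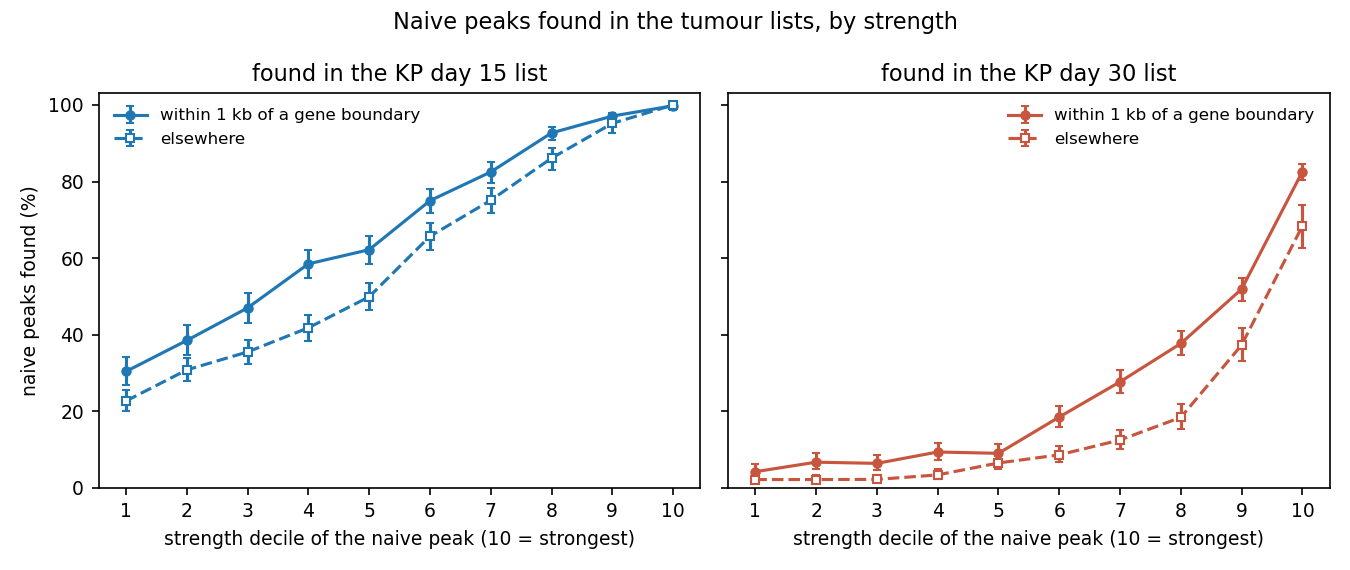
Share of naive peaks found in the KP day 15 and KP day 30 lists (percent, with 95% Wilson intervals) against the strength decile of the naive peak, for peaks within 1000 bp of a gene boundary and elsewhere. Detection at day 30 stays low in the weaker deciles (2.99% in decile 1) and reaches 80.1% in decile 10.

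Markers of other lung and immune cells had few boundary peaks in any list. Of 108 such genes, 7 had one in the naive list, 8 at day 15 and 2 at day 30, and 3 of the 108 also stand in another of the gene lists. No fibroblast or B cell gene had one. The epithelial gene Muc1 and the endothelial gene Flt1, which encodes a VEGF receptor, were gained at day 15, each as 1 gene of its list and neither was present at day 30. The T cell gene Cd3d had a boundary peak in the naive and day 15 lists. Among dendritic cell genes Xcr1 was kept at day 15, Tcf4 was in all 3 lists and Irf4 was in the naive list only. Among neutrophil genes S100a8 was in all 3 lists and Mmp8 was lost at day 30.

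The remaining members of the alveolar macrophage list, given here in full, fell into few patterns. Csf2ra, Csf2rb, Tgfbr2, Atp6v0d2, Lpl, Cd2 and Il18 had a boundary peak in the naive and day 15 lists and none at day 30. Cidec and Net1 had one in the naive list only. Siglecf, Marco, Car4, Fabp4, Chil3, Ear1, Krt79, Bhlhe41, Egr2, Plet1 and Krt19 had none in any list. Several of these had peaks farther away: 7 naive and 5 day 15 peaks were assigned to Marco, a scavenger receptor gene, as the nearest gene within 50 kb, and 1 peak assigned to Chil3 was found in all 3 lists (naive position on chromosome 3: 106170656 to 106170996). Over the whole list 66 naive peaks were assigned within 50 kb, of which 38 were found at day 15 (33.0 expected at equal strength) and 5 at day 30 (6.64 expected).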

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

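No paired analysis was possible because each group has 1 peak list, although the labels give the samples of the groups shared replicate numbers; for the same reason no sample could be left out. Motif content and its alternatives, and the choice of a single start per gene, were not run, since no genome sequence, strand or transcripts were used. The alternatives without peaks of high local background, with matching on the day 15 score, with each naive peak counted once and with matching on strength and gene boundary were chosen after seeing the data. Peak numbers kept their order on chromosomes 1 to 19 and when peaks within 500 bp were merged, and limiting to those chromosomes moved 0 of 16 values beyond their interval or 1.5 times. With the upper part of each list by score (1 in 2 peaks), 61.7% of naive peaks were found at day 15, 83.7% and 27.8% of day 15 peaks in the naive and day 30 lists, and 93.8% and 90.7% of day 30 peaks in the naive and day 15 lists. Region counts were then 3050 for naive and day 15, 2729 for naive only, 1466 for all lists and 843 for day 15 only, and boundary shares 63.5%, 68.1% and 80.8%. Genes with a boundary peak numbered 5007, 4082 and 1555, with 3614 kept at day 15, 1492 at day 30 against naive and 1443 against day 15, and 63 gained at day 30 against naive. Fewer peaks enter by construction. With lists of equal length the boundary shares were 74.2% (72.7 to 75.7), 74.8% (73.3 to 76.2) and 75.9% (74.4 to 77.3), whose intervals overlap, so that no order of the lists is shown. Overlaps were 70.6% and 60.3% of naive peaks at day 15 and day 30, 70.5% and 61.3% of day 15 peaks in the naive and day 30 lists, and 61.8% and 62.8% of day 30 peaks in the naive and day 15 lists. Regions were 668 for naive and day 15, 661 naive only, 1690 in all lists, 622 day 15 only, 324 naive and day 30, 902 day 30 only and 366 in both tumour lists. Genes numbered 2796 in the naive list and 2845 at day 15, with 2138 kept, 658 lost and 707 gained at day 15, 898 lost and 904 gained at day 30 against naive, and 877 lost and 834 gained against day 15. The alveolar macrophage list then had 1 gene in the naive list, 1 at day 15 and 1 gained, and the MHC class II list had 1 and 3. Equal lengths bring the numbers of lost and gained genes close together by construction, so these values do not show what the excess of lost genes depends on. Asking for 50% of both peaks gave 56.8% and 15.1% of naive peaks found at day 15 and day 30, 77% and 21.8% of day 15 peaks, 66.3% and 70.6% of day 30 peaks, and 2311 day 15 only, 689 day 30 only and 146 tumour-only regions. Sharing within 500 bp gave 66.6% and 23.1%, 89.0% and 30.2%, 97.7% and 95.5%, and 47 day 30 only regions. Without peaks of high local background, 85.7% of day 15 and 92.7% of day 30 peaks were found in the naive list, 153 regions were in both tumour lists only and 131 genes were gained at day 30. That choice removes 214 naive peaks, 146 of them at gene boundaries and 130 of them found at day 30, against 15 and 10 peaks of the tumour lists. Boundary shares in the order naive, day 15, day 30 were 48.7%, 54.4% and 71.6% within 500 bp, 60.8%, 65.6% and 81.3% within 2500 bp, and 47.9%, 53.5% and 71.4% for protein-coding genes only. With peaks within 50 kb, the alveolar macrophage list had 26, 22 and 5 genes with 0 gained at day 15, and the MHC class II list 14 and 15 in the naive and day 15 lists. Matching on the day 15 score put 17.6% of random lists at or above the 3 alveolar macrophage genes gained and 9.60% at or above the 3 MHC class II genes. Deciles by width gave 22.8% and 97.2% of the lowest and highest decile found at day 15 and 72.9% of the highest at day 30. Where no construction is named, the cause was not tested. Of single lists and regions, 96 of 346 values moved, 43 of them with lists of equal length and 30 with peaks within 50 kb. Depth was lowest in the naive list, with 39.2 tags per 10 kb, and at equal enrichment absence from it would mean less than absence from the tumour lists. Enrichment was not equal by the excess pileup per unit of depth. Its median over the naive value was 0.41 in the top decile of the day 15 list and 0.279 in that of day 30, where a naive peak was found. The median fold was 6.80 in the naive list, 5.65 at day 15 and 5.53 at day 30. It is taken over each list's own peaks and also depends on depth. Depth alone therefore does not tell from which list absence means least.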

Other observations

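Peaks were also assigned to genes within 50 kb, which takes in the boundary peaks as well as those farther away. Of 31 naive peaks assigned to genes of hypoxia, glycolysis and angiogenesis, 28 were found at day 15, where 22.2 were expected at equal naive strength and 0.21% of random sets had as many. The 28 were 14 of 14 peaks at gene boundaries and 14 of 17 away from them. These genes include the hexokinase gene Hk2, with 3 peaks in the naive list and 3 at day 15, and Bnip3l, with 4 and 3. Of 32 naive peaks assigned to housekeeping genes 13 were found at day 30, against 6.58 expected, with 0.37% of random sets as high, and 10 of the 13 lay at gene boundaries. Near genes of immune regulation 8 of 28 day 15 peaks were absent from the naive list, against 4.28 expected, with 4.13% of random sets as high; Pdcd1lg2, which encodes PD-L2, had 3 naive, 4 day 15 and 2 day 30 peaks. Matched also on lying at a gene boundary, a choice made after seeing the data, 0.21%, 0.8% and 4.78% of random sets were as high. With 21 lists, at most 1.05 are expected under 5% for each of these 3 measures by chance, and 1 was seen for each when matched on strength alone. Matched also on gene boundary, 2, 1 and 2 were seen, the monocyte-derived list joining at 3.59% for naive peaks found at day 15 and the endothelial list at 4.85% for day 15 peaks absent from the naive list. Hk2, Bnip3l and Pdcd1lg2 were named here after their values were seen.

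Among the genes of the sex chromosomes, all looked up after the X chromosome values were seen, Xist had no peak in any list. Ddx3y, on the Y chromosome, had 1 peak in the naive list and none at day 15 or day 30, and Kdm5d, Uty and Eif2s3y had none. On the X chromosome Eif2s3x had 2 naive peaks and none in the tumour lists, Kdm6a had 1 in all 3 lists, and Ddx3x and Kdm5c had 1 in the naive and day 15 lists.

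For the 3 patterns below, all tests except those of peak width and of X chromosome copies were chosen after the result was seen.

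The tumour lists had fewer peaks than the naive list. Fewer sequenced tags are argued against, since the day 30 list had 2.1 times the naive depth, and so is a loss limited to regions away from genes, since only 31.3% (95% interval 30.3 to 32.4) of naive peaks at gene boundaries were found at day 30. Weaker enrichment over background in the tumour libraries is a candidate explanation: of the 336 peaks in the top decile of the day 30 list, chosen on that list so that the choice does not favour the naive one, 97.9% (95.8 to 99) had a higher excess pileup per unit of depth in the naive list. The median of the day 30 over the naive excess was 0.279 at those found, and 0.41 for the top decile of the day 15 list. A difference in the cells of tumour-bearing lungs that lowers accessibility at most regions stays open and was not tested, because each group has 1 list and no value measures library quality apart from the peaks.

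Peaks away from gene boundaries were found less often at day 30, 10.7% against 31.3% of those at boundaries. At equal strength decile the difference, away minus boundary, was -7.96 percentage points (95% bootstrap interval -8.98 to -7.07). At equal decile and width quintile it was -5.28 (-6.28 to -4.32). Matching on measured strength and width thus left part of it. The decile of a measured value does not fix the underlying strength of a peak, so lower strength is not excluded. At equal strength decile the difference was also there at day 15, at -9.12 points (-10.7 to -7.62). The reverse comparison, not matched on strength, went the same way. Peaks at gene boundaries made up 58.6% of the day 15 list and 42.5% (39.9 to 45.1) of its peaks absent from the naive list. For day 30 these shares were 75.9% and 53% (44 to 61.8). Lower detection of peaks away from boundaries was therefore not limited to the tumour lists. Better keeping of boundary signal in libraries of low enrichment and a loss of distal elements in macrophages of tumour-bearing lungs cannot be told apart. No libraries of equal cells and lower enrichment were analysed here. Both explanations concern the tumour lists, whereas detection away from boundaries was lower in the naive list too, so they need not be the only ones.

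X chromosome peaks were found less often in the tumour lists than autosomal peaks, 167 of 330 at day 15 and 37 of 330 at day 30. At equal strength decile the difference at day 15 was -14.8 percentage points (95% bootstrap interval -19.4 to -10.1), which argues against lower naive strength as the whole cause. Found over expected on X was 0.778 at day 15 and 0.522 at day 30, outside the range of the 19 autosomes (0.909 to 1.08 and 0.903 to 1.17). Because X was picked after its low values were seen, this range is no separate test of a chance difference between chromosomes. Fewer X copies per cell in the tumour groups, as with another mix of male and female animals, may contribute: the median pileup over the naive pileup at shared peaks of the upper 3 deciles was 0.921 times that of other chromosomes at day 15 (0.843 to 0.964) and 0.938 at day 30 (0.845 to 1.02), an interval that includes 1. The day 15 value lies between those set in advance for and against it, only peaks found in both lists enter it, and the labels used here give no sex, so it cannot be told apart from a change of the X chromosome in the macrophages. More male animals would also bring more Y chromosome signal, whereas the naive list had 1 peak on Y and the tumour lists 0, which runs against it but is too few to exclude it.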
